A study of Mus musculus with 20 samples.

How the data were processed

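Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in Comma-Dβ cells, a mouse mammary epithelial cell line, at passage 28. Per the labels, 20 samples fell into 5 groups of 4 replicates, made with antibodies to HEB, H3K27ac, H3K4me3 and H3K27me3 and from input chromatin. HEB is the basic helix-loop-helix E protein encoded by Tcf12. Cells grew in DMEM/F12 medium with 2% fetal bovine serum, 10 mM HEPES, 0.125 IU/mL insulin and 5 ng/mL epidermal growth factor, per the labels, and libraries were made with an Illumina TruSeq ChIP kit.

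The deposited data analysed here were 4 peak lists, 1 per antibody, in mm10 coordinates per the submitters' processing notes, which also name SAMtools without a version. The aligner, the peak caller and the way the 4 replicates were combined are not given in the sources used here. The HEB list holds positions only, and its deposited name describes a consensus of replicates with a minimum overlap of 2. The 3 histone mark lists have the broadPeak layout, with peak names of the form that MACS2 writes. Their deposited score is 10 times the −log10 q-value as a whole number, checked on the values, where at most 5 peaks of a list differed, and it was not used further. The deposited fold enrichment of each peak is a ratio of ChIP over control, and which input served as control is not given in the sources used here. The deposited −log10 p-value and −log10 q-value of each peak are the authors' own. All of these per-peak values belong to the authors' lists, and they were used to describe, rank, filter and compare peaks within a list, also in tests. Because there is 1 list per antibody and it carries no column per replicate, no spread between replicates could be computed, and read depth per sample is unknown. Every p-value below therefore compares positions or genes within these lists, and every interval covers counting error only. The labels call the 4 replicates of a group biological.

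The overlap of HEB sites with each mark counted a site as overlapping at 1 bp or more. It was compared with 10000 random placements that kept each site's width and its chromosome or scaffold, two-sided, so that the smallest possible p was 0.0002. Assembly gaps were not used here, so placements ran between the first and last peak of each sequence over the 4 lists. Shared base pairs of mark pairs were divided by the expectation from both coverages and compared with 1000 circular shifts along each chromosome, two-sided, with a smallest possible p of 0.002. Shares of sites have Wilson 95% confidence intervals.

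Gene positions came from an NCBI RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 is based on, with 21887 protein-coding genes on the numbered chromosomes, X and Y. Strand, transcripts and exons were not used here. The planned promoter windows around transcript starts were therefore replaced by windows of 1 kb around both ends of each gene, called gene ends, and exons and introns were not separated. A gene end with a mark can be the start or the finish of its gene, and when a gene carries 2 marks these can lie at opposite ends. A planned test of E-box hexamers was not run because no genome sequence was used here. Each HEB site was assigned to the gene with the nearest gene end, at most 100 kb away. The 21 gene lists covered mammary lineages (basal identity, myoepithelial contractile, luminal progenitor, luminal hormone sensing, epithelial adhesion), extracellular matrix, cytoskeleton and focal adhesion, E proteins and Id proteins, EMT, Notch, Wnt, Hox genes, regulators of other lineages, cell cycle, housekeeping, and markers of immune, endothelial, adipocyte, stromal fibroblast, neuronal and skeletal muscle cells. Some genes stand in more than 1 list. Marks and sites were tested over these lists with two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 63 tests of lists and marks and over 21 tests of lists and HEB sites, at a threshold of 0.05. All 429 distinct genes of the lists were found in the table. H3K27ac peaks with and without HEB were compared by the difference of median fold enrichment. Each peak with HEB had 5 peaks without HEB drawn among the 25 unused ones nearest in width, a number set after the data were seen, and the difference was tested with 100000 permutations, two-sided, with a smallest possible p of 1e-05. The permutations and the bootstrap interval treated the peaks with and without HEB as 2 pools. They did not keep each peak with its matched set.

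The lists, the tests and most alternatives were fixed before the data were examined. The alternatives changed the overlap rule, the peak threshold (−log10 q of 5 or more, or the peaks above the median fold), the placement, the site size, the chromosomes, the window (500 or 2500 bp), the assignment to genes and the matching. Alternatives without scaffolds, Y and chromosome ends, without chromosomes 5 and 15, and on autosomes only for the tests over genes were added after seeing the data. Named genes follow a rule fixed beforehand. The rule takes up to 30 members of the lists with an HEB site in order of distance and, for each list and mark, up to 4 members with the widest peak. It also takes the genes at the 5 widest peaks of each mark, the 10 genes with the most HEB sites, the genes at the 10 HEB sites in the H3K27ac peaks of highest fold, and Tcf12. Genes named outside it are said to be so. A gene that the rule takes is not reported here.

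The placement test was checked on simulated data. With 956 sites placed at random and each set tested on 3 marks, 5.67% of 300 tests gave p under 0.05. With 30 percent of the sites moved onto H3K27ac peaks, the overlap was 0.995 of that expected from the moved sites and the background. Random sites came from the same placement as the test, so this checks the calculation and not the placement as a model. The Fisher test on random lists of 46 genes drawn from 21000 passed 0.05 in 3.2% of 500 runs, and in 96.8% of runs when the list had 5 times the background share. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are printed 1-based in mm10.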

Results

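Chromatin immunoprecipitation with sequencing was done on 20 samples, in 5 groups of 4 (HEB, H3K27ac, H3K4me3, H3K27me3 and input chromatin). The 4 deposited peak lists described where HEB, an E protein transcription factor, and the histone marks H3K27ac, H3K4me3 and H3K27me3 lay in Comma-Dβ mouse mammary epithelial cells. H3K27ac marks active promoters and enhancers, H3K4me3 marks promoters, and H3K27me3 is the mark laid down by Polycomb complexes at silenced genes. The HEB list held 956 sites with a median width of 438 bp, of which 887 lay on the numbered chromosomes, X and Y. The H3K27ac list held 61496 peaks covering 120.1 Mb, with a median fold enrichment of 2.39. The H3K4me3 list held 17162 peaks over 32.7 Mb at a median fold of 12.9, and the H3K27me3 list 114660 peaks over 379.1 Mb at a median fold of 1.74. Peaks with a −log10 q of 5 or more made up 87.8% of the H3K4me3 list, 45.0% of the H3K27ac list and 9.53% of the H3K27me3 list. Each list stands for 4 replicates of an antibody, combined in a way that is not fully given, read depth per sample is unknown, and no value below has a replicate error.

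The first comparison asked which chromatin HEB occupied. HEB sites lay mostly in H3K27ac peaks, less often in H3K4me3 peaks, and seldom in H3K27me3 peaks. H3K27ac was present at 815 of 956 sites (85.3%, Wilson 95% interval 82.9 to 87.4), including sites next to the collagen gene Col16a1, the focal adhesion gene Pxn, the EMT regulator Snai1 and the keratin gene Krt8. H3K4me3 was present at 224 sites (23.4%, 20.9 to 26.2), among them the sites at Col16a1, Pxn, Cnn2 and Lfng. H3K27me3 was present at 90 sites (9.41%, 7.72 to 11.4). On the numbered chromosomes, X and Y, 577 of 887 sites (65.1%) carried H3K27ac alone of the 3 marks, 163 (18.4%) carried H3K27ac with H3K4me3, 22 carried all 3 marks, 24 carried H3K27me3 alone and 85 (9.58%) carried none.

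Random placements of the same sites overlapped H3K27ac in 9.37% ± 0.863 (SD over 10000 placements), H3K4me3 in 4.29% ± 0.545 and H3K27me3 in 18.1% ± 1.22. The observed shares were 9.10 times, 5.46 times and 0.520 times these means, each at p = 0.0002 (n = 956 sites), the smallest the two-sided placement test can give. On autosomes only, these ratios were 13.2, 12.0 and 0.345. Against placements 20 to 100 kb from each site the ratios were 4.62 for H3K27ac, 3.63 for H3K4me3 and 0.643 for H3K27me3. With peaks above the median fold of their list they were 14.2, 4.71 and 0.298. For H3K4me3 this was lower than the 5.46 with all peaks, and 56 sites (5.86%) overlapped against 224. The H3K27me3 ratio was nearest to 1 with peaks of −log10 q of 5 or more, at 0.744 (n = 956 sites, p = 0.0222, and 0.0002 to 0.0222 over its alternatives).

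**Figure D1:**
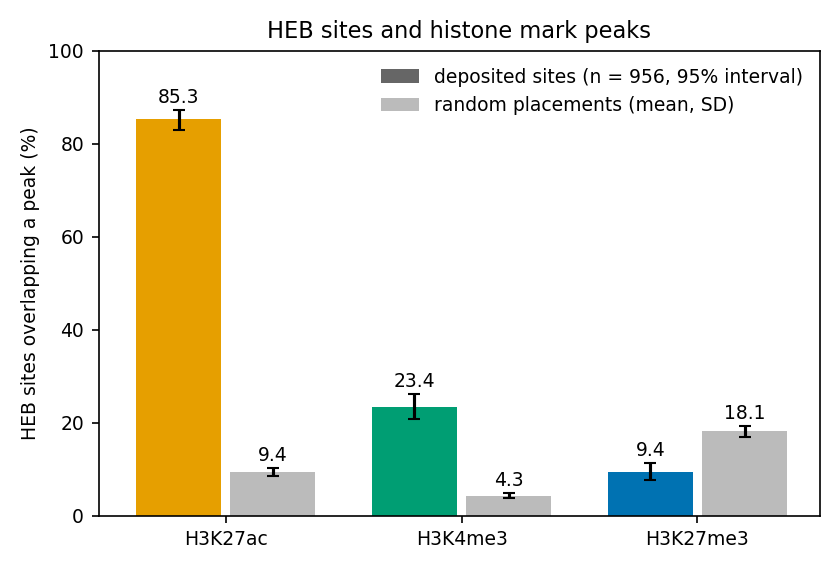
Share of the 956 HEB sites that overlap a peak of each histone mark, in percent (coloured bars, Wilson 95% intervals), beside the mean of 10000 random placements (grey bars, SD). HEB sites stand above placement for H3K27ac (85.3 against 9.37%) and H3K4me3 (23.4 against 4.29%), and below it for H3K27me3 (9.41 against 18.1%).

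The next comparison asked whether H3K27ac peaks that hold HEB differ in strength from those that do not. HEB sites lay in strong H3K27ac peaks. The highest folds at an HEB site were 15.3 in Rtkn (chromosome 6, 83136946 to 83138232), 13.6 in Tnrc18 and 13.4 at a site 29.8 kb from Crabp1, a retinoic acid binding protein gene. Sites near Junb, an AP-1 transcription factor gene, and beside the linker histone genes H1f4 and H1f2 lay in peaks with folds of 12.5, 12.5 and 11.8. The other sites among the 10 strongest were assigned to Gm46353, 2310022B05Rik, Azin1 and 1700001O22Rik. The 747 H3K27ac peaks with HEB were 1.22% of 61444 such peaks, and 35.3% of them ranked in the top 10 percent by fold.

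The median fold was 4.34 (interquartile range 3.02 to 6.01) in the 747 peaks with HEB and 3.70 (2.58 to 5.25) in 3735 peaks without HEB matched on width. The difference was 0.635 (bootstrap 95% interval 0.390 to 0.868, two-sided permutation test, p = 1e-05, the smallest it can give). Without matching the difference was 1.96, and peaks with HEB had a median width of 3598 bp and other peaks one of 1314 bp.

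The next comparison located HEB sites relative to genes. Sites mostly lay away from gene ends, as at Id3, an inhibitor of E proteins, where 3 sites lay 3.32, 26.7 and 33.1 kb from the gene (chromosome 4, 136140262 to 136140742, 136116819 to 136117427 and 136110549 to 136111004). Col18a1, a basement membrane collagen gene, had 2 sites within the gene and 1 at 40.5 kb from it. Close sites included Col16a1 at 0.027 kb, Pxn at 0.106 kb and Snai1 at 0.759 kb from a gene end. Of 887 sites, 69 (7.78%) lay within 1 kb of a gene end, 368 (41.5%) inside a gene and 450 (50.7%) between genes.

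Placements put 3.19% ± 0.583 within 1 kb of a gene end, and the observed share was 2.44 times that (n = 887 sites, p = 0.0002). The share between genes was 0.884 times the 57.4% of placements (n = 887 sites, p = 0.0002), and that inside genes did not pass the test (1.05 times, p = 0.231). These directions turned against midpoints of H3K27ac peaks, drawn without matching on width. Of these midpoints, 14.3% lay within 1 kb of a gene end, 49.5% inside genes and 36.2% between genes. Against that background the HEB share was 0.543 times at gene ends, 0.839 times inside genes and 1.40 times between genes (n = 887 sites, p = 0.0002 each). Counted by whole peaks, 20.6% of the 747 H3K27ac peaks with HEB reached within 1 kb of a gene end, against 19.2% of the others. This count was also not matched on width, and peaks with HEB were wider (median 3598 bp against 1314 bp). A wider peak has more room to reach a gene end. The count therefore cannot tell whether HEB avoided H3K27ac peaks at gene ends.

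**Figure D2:**
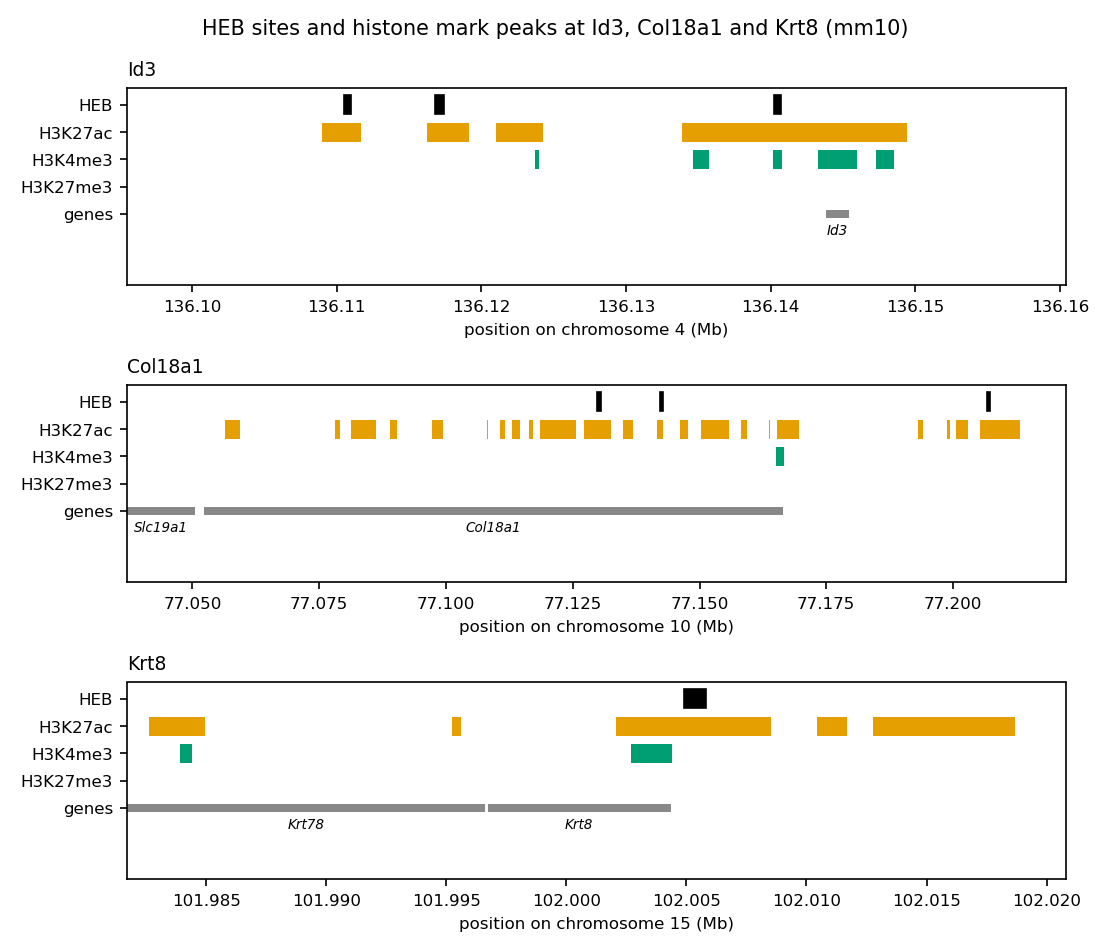
HEB sites and histone mark peaks (coloured boxes, to scale) with protein-coding genes (grey) at Id3, Col18a1 and Krt8, against position in Mb in mm10. The 3 HEB sites of Id3, the 3 of Col18a1 and the 1 of Krt8 each lie in an H3K27ac peak.

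The gene lists asked which gene groups lay next to HEB sites. Of the 21 lists, that of extracellular matrix genes, also the longest, had the largest number of genes with a site. By share the E protein and Id list stood higher, at 2 of 7 genes (28.6%). HEB sites were assigned to 12 of 46 matrix genes (26.1%, against 2.96% of other protein-coding genes), among them the fibrillar collagen genes Col1a1, Col1a2, Col3a1 and Col5a1, the basement membrane genes Col4a1, Col4a2, Col18a1 and Hspg2, and Sparc. Sites were assigned to 5 of 22 Notch pathway genes (22.7%), namely the receptor genes Notch1 and Notch2, the target Hes1, the glycosyltransferase gene Lfng and the coactivator gene Maml3. The cytoskeleton and focal adhesion list had 5 of 32 genes (15.6%), which were Pxn, Tns3, Rhob, Actn1 and Rnd3, and the epithelial adhesion list 3 of 15, which were Krt8, Cdh1 and Epcam. Maml3, Rnd3 and Epcam lay beyond the 30 nearest and were named after their values were seen.

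In all, 759 of the 887 sites lay within 100 kb of a gene end and were assigned to 658 genes (3.01% of protein-coding genes), at a median distance of 22.3 kb for the 887 sites. By Fisher exact tests adjusted over 21 lists, the matrix list passed at p = 1.58e-07, the Notch list at p = 0.00437, the cytoskeleton list at p = 0.0174 and the epithelial adhesion list at p = 0.0493. All 4 calls ended when the background was sites drawn from H3K27ac peaks at similar distances from gene ends. The drawn peaks were not matched on width or fold. In those draws (n = 10000) the matrix list held 5.81 ± 2.18 genes against the 12 observed (adjusted p = 0.307, and 3.12e-08 to 0.307 over its alternatives), the Notch list 1.76 ± 1.20 against 5 (adjusted p = 0.386), the epithelial adhesion list 1.16 ± 1.00 against 3 (adjusted p = 0.910) and the cytoskeleton list 4.24 ± 1.81 against 5 (adjusted p = 1). With sites at most 10 kb from a gene end 273 genes had a site and no list passed the Fisher exact test (matrix, 4 of 46, odds ratio 7.64 against 11.6 within 100 kb, adjusted p = 0.0538), and with sites inside the gene or within 10 kb of it the matrix list alone did (7 of 46, adjusted p = 0.00609).

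Other lists did not pass. The E protein and Id list had 2 of 7 genes, Id3 and Id2 (Fisher exact, adjusted p = 0.072), and the Wnt list 3 of 26, Wnt10a, Wnt7b and Tcf7l1 (adjusted p = 0.146). Endothelial markers had 2 of 12, Flt1 and Cdh5, the latter named after its value was seen (Fisher exact, adjusted p = 0.146), and stromal fibroblast markers 2 of 13, the collagen genes Col1a1 and Col3a1 that the matrix list also holds (adjusted p = 0.148). Single genes with a site were Cnn2 of the 18 myoepithelial contractile genes, Lif of the luminal progenitor list, Snai1 of the EMT list, Mb of the skeletal muscle list, Ywhaz of the housekeeping list and Myc of the cell cycle list. No site was assigned to any of the 22 basal identity genes, the 16 luminal hormone sensing genes, the 39 Hox genes or the 40 regulators of other lineages, nor to the immune, adipocyte and neuronal markers. With 3.01% of protein-coding genes assigned a site, none of these lists passed as lower. Counting every gene end within 100 kb, sites lay near 3 basal identity genes (13.6% against 11.8% of other genes) and 1 hormone sensing gene. That count also put sites near 2 regulators of other lineages and 2 immune markers, and near none of the Hox genes, adipocyte or neuronal markers. Krt8, Wnt7b, Mb, Ywhaz and Myc lie on chromosome 15, where 71 H3K27ac peaks held HEB against 43.8 for an even rate over the autosomes (Fisher exact, p adjusted over 19 chromosomes = 0.0015). Without chromosomes 5 and 15, an alternative added after seeing the data, the epithelial adhesion list did not pass with fewer genes tested (2 of 9, odds ratio 10.2 against 8.10 with all chromosomes, Fisher exact, adjusted p = 0.0995), and the matrix, Notch and cytoskeleton lists did.

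Among the genes with the most sites were Rxra, a retinoid receptor gene, and Gse1 with 4 each, and all of these sites lay in H3K27ac peaks. Pxn and Lfng lie on chromosome 5, where 68 H3K27ac peaks held HEB against 56.8 for an even rate, which did not pass (Fisher exact, p adjusted over 19 chromosomes = 0.288). Gm52481 on the Y chromosome had 5 sites, all in H3K27ac peaks, and C130026I21Rik and Gm15319 had 4 each, of which 0 and 2 lay in H3K27ac peaks. The Y held no other HEB site and only 14 H3K27ac, 11 H3K4me3 and 2 H3K27me3 peaks. Its HEB sites lay from 90737834 to 90813920, near the last peak position of the Y (90829350). Whether they reflect binding was not tested. Id3 and Zcchc24 had 3 each, all in H3K27ac peaks, and Scaf8 and Sfi1 had 3 each with 1 in an H3K27ac peak, beginning at the first peak position of chromosomes 17 and 11. Tcf12, which encodes HEB, had no site assigned, and it carried H3K4me3 (3229 bp wide) and H3K27ac (1918 bp) at a gene end without H3K27me3.

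The marks were then compared with each other. H3K27ac and H3K4me3 lay together and both were depleted of H3K27me3. They shared 23.7 Mb, which was 72.6% of the H3K4me3 base pairs and 15.8 times the expectation from both coverages. H3K27ac and H3K27me3 shared 2.14 Mb, 0.123 times the expectation, and H3K4me3 and H3K27me3 shared 2.55 Mb, 0.540 times the expectation. Each lay outside all circular shifts (two-sided, n = 1000 shifts, p = 0.002, the smallest they can give). For H3K4me3 and H3K27me3 the ratio to the expectation was 0.926 with peaks of −log10 q of 5 or more. It was 0.128 with peaks above the median fold. At the q threshold the shared base pairs were 0.8346 times the mean of the shifts, and the lowest shift was 0.8364 times it. That result therefore lay only just outside the shifts. H3K4me3 peaks that overlapped H3K27me3 were 2665 of 17112, with a median fold of 4.97 against 15.8 in the others. Counted by peaks, the ratio for H3K27ac and H3K4me3 was 8.13 and that for H3K27ac and H3K27me3 was 0.20.

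The widest H3K27ac peaks spanned Nfix (91.9 kb), Myh9, the nonmuscle myosin heavy chain gene (69.4 kb), and Frmd8 (61.8 kb), and 1 of 56.4 kb reached Niban2 and Lrsam1. A peak of 58.3 kb on chromosome 15 (85651808 to 85710143) touched no protein-coding gene end and held the widest H3K4me3 peak of the list, 24.4 kb (85663310 to 85687667). The next widest H3K4me3 peaks were at Gata3 (21.7 kb), a luminal transcription factor gene, Brinp3 (16.6 kb), Tfap2a (16.0 kb) and Zfp503 (14.1 kb). The widest H3K27me3 peaks reached Tfec (216.6 kb), Sox1 (211.7 kb), Rnf220 (206.4 kb), Rxrg and Lmx1a (204.5 kb) and Rbfox3 (188.6 kb).

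At the gene ends of 21887 protein-coding genes, H3K4me3 with H3K27ac and without H3K27me3 was the most frequent state, with 9480 genes (43.3%), including Gapdh, Rpl13a and Krt14. H3K27me3 alone marked 4470 genes (20.4%), including Foxa1, Sox10 and Myod1, and 4178 had none of the marks. H3K4me3 and H3K27me3 without H3K27ac were found at 1132 genes, among them Dll3, Kit and Aldh1a3, and all 3 marks at 1190, among them Ccnd2 and Cldn7.

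Of genes with H3K4me3, 2322 of 12213 also had H3K27me3, against 49.1% of genes without H3K4me3 (odds ratio 0.244, 95% interval 0.229 to 0.259). Of genes with H3K27ac, 10670 of 11696 (91.2%) had H3K4me3, against 15.1% of the others (odds ratio 58.3, 53.6 to 63.4). Both Fisher exact p-values were below the smallest number that double precision holds.

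The fixed lists differed in their marks, with 32 of 63 tests past the adjusted threshold. Genes of the actin cytoskeleton and focal adhesions carried the active marks. H3K4me3 lay at 31 of 32 (Fisher exact, adjusted p = 3.94e-06), H3K27ac at 29 (p = 0.000111) and H3K27me3 at 3 (p = 0.0109), with H3K27ac peaks of 69.4 kb at Myh9, 46.9 kb at Actn4 and 41.8 kb at Itga3. Matrix genes carried H3K27ac at 37 of 46 and H3K4me3 at 38 of 46 (Fisher exact, both adjusted p = 0.000773), with H3K27ac peaks of 26.4 kb at Col1a1, 26.3 kb at Timp3 and 20.8 kb at Thbs1. H3K27me3 lay at 13 matrix genes and did not pass, with peaks of 29.2 kb at Eln and 29.1 kb at Nid2. EMT and mesenchymal genes had each active mark at 14 of 15 (Fisher exact, adjusted p = 0.00501 for H3K27ac and 0.00879 for H3K4me3) and H3K27me3 at 2, with wide H3K27ac at Vim (13.9 kb), Snai1 (9.15 kb) and Prrx1 (6.81 kb).

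All 7 E protein and Id genes had H3K27ac (Fisher exact, adjusted p = 0.0349) and H3K4me3 (p = 0.0396) and none had H3K27me3, with H3K27ac peaks of 15.6 kb at Id3 and 9.10 kb at Id2. Housekeeping genes had each active mark at 19 of 20 (Fisher exact, adjusted p = 0.000773) and H3K27me3 at 1, Hprt (p = 0.0184). Cell cycle genes had H3K27ac at 22 and H3K4me3 at 23 of 24 (Fisher exact, adjusted p = 0.000731 and 0.000274), the widest at Ccnd1 for H3K27ac and at Cdkn1b for H3K4me3, and H3K27me3 at 3 (p = 0.0802). With peaks of −log10 q of 5 or more, which left H3K27me3 at 17.1% of other genes, its calls ended for the cytoskeleton list (1 of 32, Fisher exact, adjusted p = 0.0637, and 0.0066 to 0.0637 over its alternatives) and the housekeeping list (0 of 20, 0.0677, and 0.00594 to 0.0677). The ratio to other genes was not nearer to 1 with those peaks, at 0.183 against 0.290 for the cytoskeleton list and 0 against 0.155 for the housekeeping list. With a window of 2500 bp the H3K4me3 call ended for the E protein and Id list (7 of 7 as before, Fisher exact, adjusted p = 0.0836, and 0.0351 to 0.0836).

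Epithelial adhesion genes carried both active and repressive marks in these lists, and whether the marks shared a cell or an allele was not tested. H3K27ac lay at 15 of 15 (Fisher exact, adjusted p = 0.000731), H3K4me3 at 14 (p = 0.00879) and H3K27me3 at 10 (p = 0.023), and these 10 had all 3 marks. At Cdh1, the E-cadherin gene on chromosome 8, H3K27ac spanned 106602332 to 106605028 and H3K27me3 106602313 to 106604711, and both covered the same gene end. H3K27me3 peaks of 15.2 kb at Esrp1, a splicing regulator gene, and 11.9 kb at Grhl2, an epithelial transcription factor gene, also overlapped H3K27ac and H3K4me3 peaks. The H3K27me3 call ended with a window of 2500 bp (1.74 times the share of other genes against 2.07 times with 1 kb, Fisher exact, adjusted p = 0.0607, and 0.00501 to 0.0607 over its alternatives).

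Mammary lineage lists were mixed. Of the 16 luminal hormone sensing genes, 10 had H3K27me3 (Fisher exact, adjusted p = 0.0326), 9 had H3K27ac and 12 had H3K4me3, which passed as higher with a window of 2500 bp (adjusted p = 0.0449, and 0.0449 to 0.508 over its alternatives). On autosomes only, with 8 of 14 genes, the H3K27me3 call ended at 1.83 times the share of other genes against 1.94 times with all chromosomes (Fisher exact, adjusted p = 0.0784, and 0.0141 to 0.0784). H3K27me3 domains were 32.1 kb at the prolactin receptor gene Prlr and 28.3 kb at Foxa1, whereas Gata3 had H3K27ac over 30.6 kb and Tbx3 over 7.99 kb. Basal identity genes had H3K27ac at 14, H3K4me3 at 15 and H3K27me3 at 8 of 22, and no mark passed. Among them H3K27ac peaks were 13.9 kb at Vim, 10.1 kb at Sox9 and 8.85 kb at Krt14, while Irx4 lay in 10.8 kb of H3K27me3. At the basal keratin gene Krt5 (chromosome 15), an H3K27ac peak from 101708969 to 101719641 overlapped the edge of an H3K27me3 peak from 101692297 to 101709121. Myoepithelial contractile genes had H3K27ac at 9, H3K4me3 at 12 and H3K27me3 at 8 of 18, with H3K27ac over 17.1 kb at Cald1 and 16.0 kb at Tpm1, and H3K27me3 over 17.5 kb at the oxytocin receptor gene Oxtr and 13.3 kb at Des. Luminal progenitor genes had each active mark at 10 and H3K27me3 at 8 of 18, with the milk protein gene Lalba in 45.2 kb of H3K27me3 and Lif with 15.4 kb of H3K27ac. Stromal fibroblast markers had H3K27ac at 7, H3K4me3 at 4 and H3K27me3 at 5 of 13. No test passed for these 3 lists.

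Signalling lists carried H3K4me3, at 21 of 26 Wnt genes (Fisher exact, adjusted p = 0.0232) and 18 of 22 Notch genes (p = 0.0348), and H3K27ac at 15 Wnt and 14 Notch genes, which did not pass. H3K27me3 lay at 16 Wnt genes (Fisher exact, adjusted p = 0.00852), with domains of 90.2 kb at Wnt7a, 44.0 kb at Rspo1 and 34.2 kb at Lef1, and at 12 Notch genes, which did not pass (p = 0.0675), with 29.7 kb at Heyl. The H3K4me3 call of the Notch list ended in 4 of its alternatives, among them a window of 500 bp (1.43 times the share of other genes against 1.47 times with 1 kb, Fisher exact, adjusted p = 0.0596, and 0.0217 to 0.0637 over its alternatives), and that window also ended the call of the Wnt list (1.42 against 1.45 times, adjusted p = 0.054, and 0.0217 to 0.054).

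H3K27me3 often lay at genes of other lineages, although the endothelial and skeletal muscle lists did not pass the test for it. It lay at 38 of 40 regulators of other lineages (Fisher exact, adjusted p = 4.86e-15), with domains of 211.7 kb at Sox1, 158.7 kb at Pax5 and 151.1 kb at Pax2, while H3K27ac lay at 3 (p = 2.67e-08) and H3K4me3 at 9 (p = 0.000224). Neuronal markers had H3K27me3 at 11 of 13 (Fisher exact, adjusted p = 0.000773), H3K4me3 at 5 and H3K27ac at 1, Map2 (p = 0.00444). Immune markers had H3K27me3 at 12 of 18 (Fisher exact, adjusted p = 0.0109), with 43.2 kb at Lyz2, H3K4me3 at 3 (p = 0.00475) and H3K27ac at 5 (p = 0.0623). Adipocyte markers had H3K27me3 at 7 of 10 (Fisher exact, adjusted p = 0.0348), H3K27ac at 3 and H3K4me3 at 4. Endothelial markers had H3K27ac at 1 of 12, Pecam1 (Fisher exact, adjusted p = 0.00725), H3K4me3 at 3 (p = 0.0715) and H3K27me3 at 7 (p = 0.109), with 89.1 kb at Vwf. Skeletal muscle markers had H3K4me3 at 3 of 15 (Fisher exact, adjusted p = 0.0184), H3K27ac at 5 and H3K27me3 at 9 (p = 0.0533), with 41.2 kb at Myog. With peaks of −log10 q of 5 or more the H3K27me3 call of the immune list ended (4 of 18, Fisher exact, adjusted p = 0.621, and 0.00947 to 0.621 over its alternatives) and the endothelial list gained 1 (7 of 12 against 17.1% of other genes, 0.00501, and 0.00501 to 0.113), and with a window of 2500 bp that of the adipocyte list ended (7 of 10 against 38.3% of other genes, 0.0844, and 0.0188 to 0.0844). Some tests above the threshold passed in alternatives: H3K4me3 as lower at endothelial markers in 3 of 5 (Fisher exact, adjusted p = 0.0347 to 0.0665 over all), H3K27ac as lower at immune markers with windows of 500 and 2500 bp (0.0351 to 0.0975), and H3K27me3 as higher at skeletal muscle markers on autosomes only (0.0477 to 0.455).

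Hox genes carried H3K27me3 at 34 of 39 (Fisher exact, adjusted p = 5.44e-11), and H3K27ac at 16 and H3K4me3 at 19, which did not pass. This p counts 39 genes as independent although they lie in 4 clusters and neighbours share peaks, so it may be too small. The Hoxd cluster was covered by H3K27me3 over 97.9% of its length with no H3K27ac or H3K4me3 at any of its 9 genes, and all 9 genes of the Hoxc cluster lay in a single peak of 181.6 kb (chromosome 15, 102891508 to 103073067). In the Hoxb cluster, an H3K27ac peak of 18.3 kb spanned Hoxb2 and Hoxb3, and 8 of 10 genes had H3K27ac. In the Hoxa cluster, 6 of 11 genes had H3K27ac and 9 had H3K27me3. The split by cluster was made after the values were seen, and differences between clusters were not tested.

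**Figure D3:**
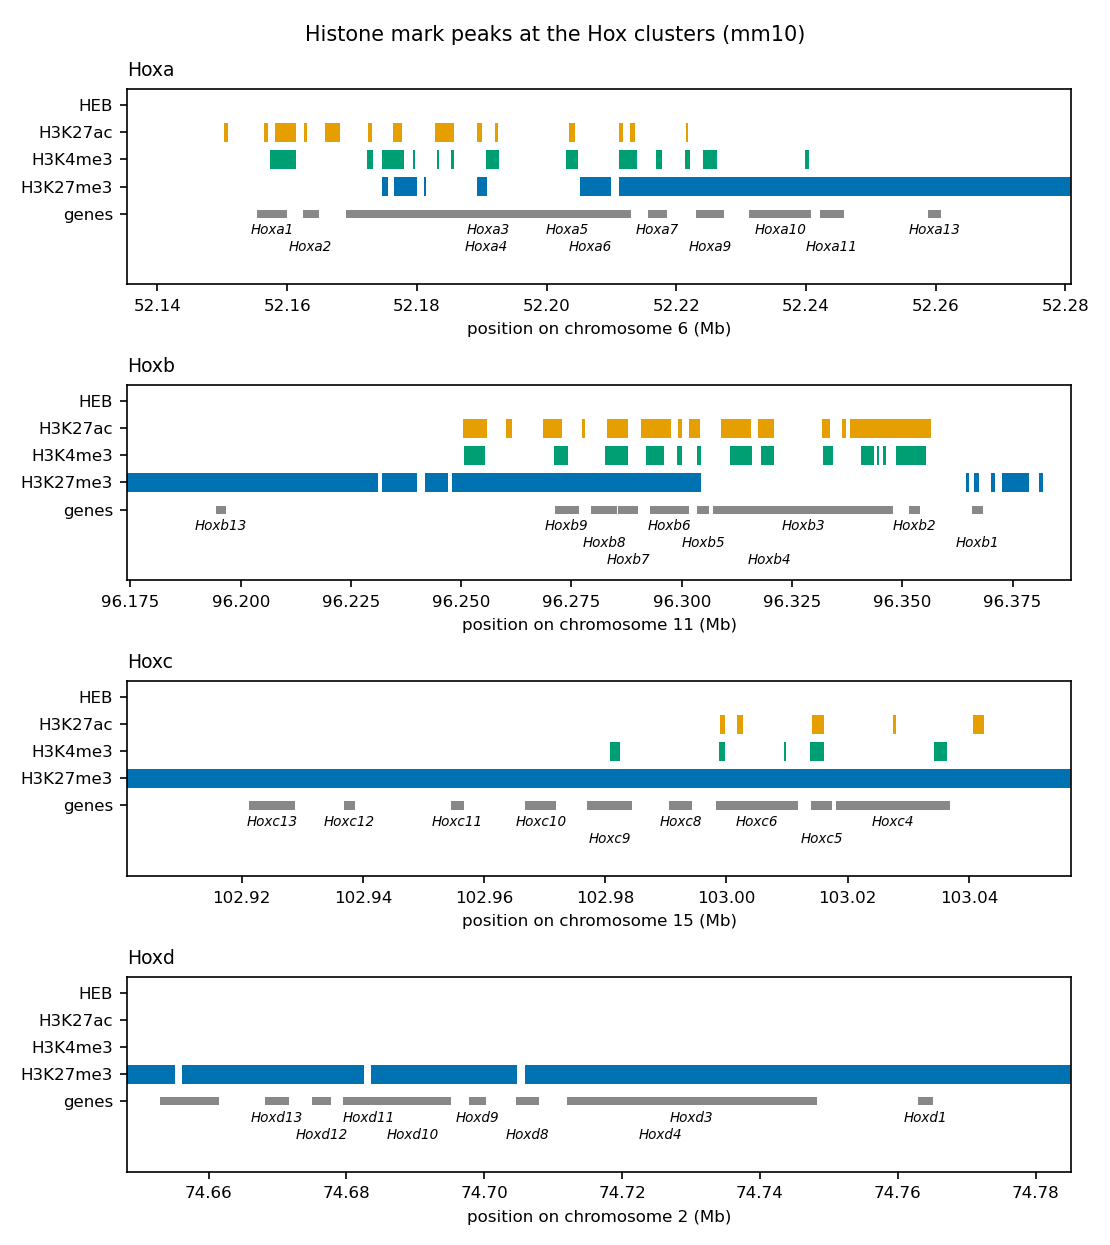
Histone mark peaks (coloured boxes, to scale) and Hox genes (grey) in the 4 Hox clusters with 20 kb on either side, against position in Mb in mm10; no HEB site lies in these regions. H3K27me3 covers the Hoxc and Hoxd clusters (100% and 97.9% of their length), and 57.4% of Hoxa and 62.1% of Hoxb, where H3K27ac covers 14.8% and 33.6%.

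**Figure D4:**
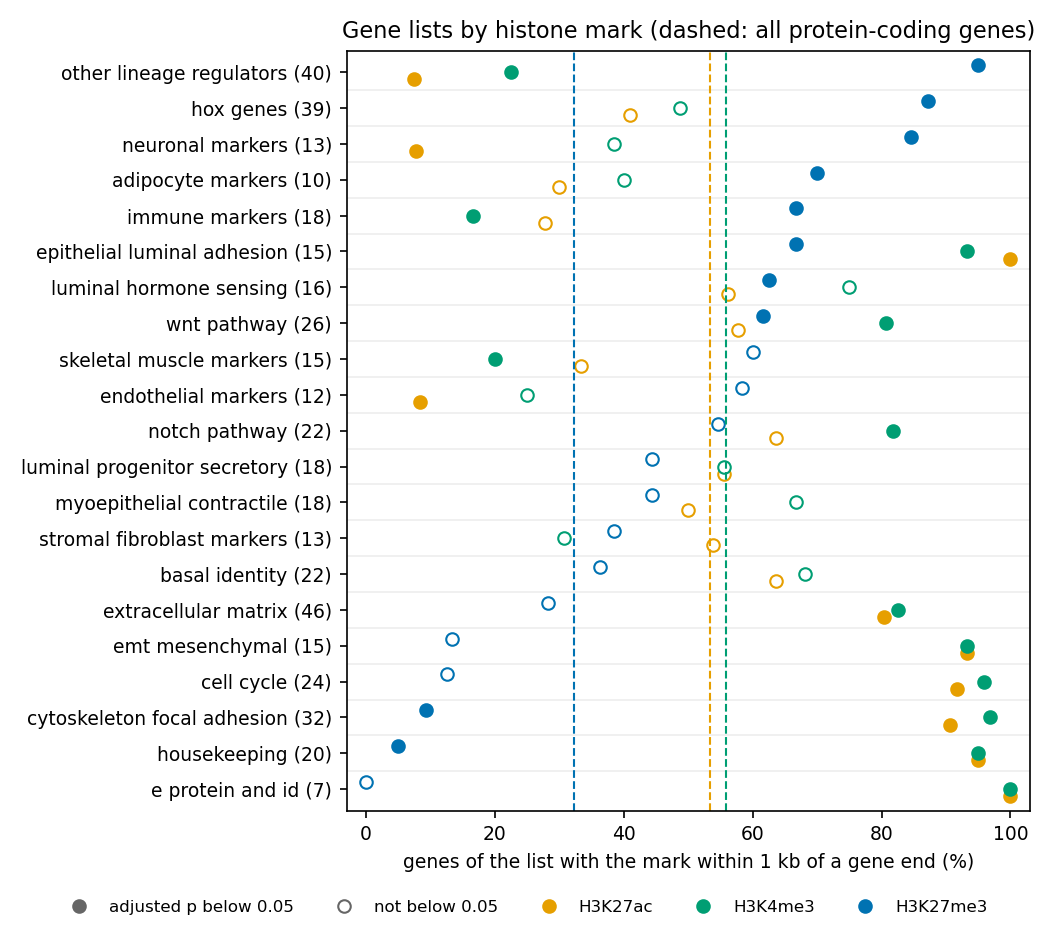
Percent of the genes of each list (number of genes in brackets) with each mark within 1 kb of a gene end. Filled points passed the Fisher exact test at an adjusted p below 0.05, open points did not, and dashed lines give all protein-coding genes (53.4% for H3K27ac, 55.8% for H3K4me3, 32.3% for H3K27me3).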

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

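The test in this part was chosen only after the result was seen. Of the 956 HEB sites, 69 (7.22%) lay on 8 unplaced scaffolds, which no comparison with genes used. On these scaffolds 45 of the 69 sites were on 1 of them, and the median site width was 1053 bp against 426 bp elsewhere. All 3 histone marks were present at 29 scaffold sites (42.0%, Wilson 95% interval 31.1 to 53.8), against 2.48% of the 887 other sites.

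A candidate explanation is collapsed repeats, where reads from many copies pile up and give high significance at a modest fold. Scaffold peaks had a median −log10 p 2.77 times (H3K27ac), 1.76 times (H3K4me3) and 1.285 times (H3K27me3) that of autosome peaks of the same fold and width. A ratio over 1.5 in each mark was required and 2 of the 3 marks reached it, so this explanation stays open, and no biological explanation was tested.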

How the results depend on the processing

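Alternatives without scaffolds, Y and chromosome ends, without chromosomes 5 and 15, and on autosomes only for gene pairs and for marks at lists were chosen after seeing the data. Over 14 main results and 71 alternatives, 65 kept their direction and side of the threshold, or stayed within 1.5 times for counts. Over these, the overlap ratios ranged from 4.62 to 14.2 for H3K27ac, 3.63 to 12.0 for H3K4me3 and 0.298 to 0.744 for H3K27me3, and the count of tests passed by lists and marks from 30 to 32. The count of 4 lists with HEB sites became 0 with a gene end at most 10 kb away, where 273 genes had a site against 658 and the odds ratios were 7.64 against 11.6 for the matrix list, 7.97 against 9.55 for Notch, 5.31 against 6.01 for the cytoskeleton and 5.67 against 8.10 for epithelial adhesion. It became 1 with sites in the gene or within 10 kb of it (620 genes), where these ratios were 6.22, 5.44, 4.93 and 5.29, and the cause was not tested. It became 0 against sites drawn from H3K27ac peaks without matching on width or fold, a background that already lies near genes of these lists. It was 3 without chromosomes 5 and 15, where the odds ratio of epithelial adhesion was 10.2 with fewer genes tested (9 against 15). With every gene end within 100 kb 5 lists passed, the same 4 as higher and the Hox list as lower (0 of 39). The Hox genes lie in 4 clusters, so this Fisher exact test counts neighbours that share sites as independent, and its call is not firm. Against midpoints of H3K27ac peaks, not matched on width, the location ratios turned to 0.543 at gene ends, 0.839 inside genes and 1.40 between genes. That background puts 14.3% of midpoints near a gene end against 3.19% for random placement. Of 420 alternatives for single lists, 24 lost and 9 gained a call, and 0 reversed. The E-box test and its alternatives were not run. No paired analysis was possible because there is 1 list per antibody and its columns carry no replicate numbers, so no replicate was left out in turn. Read depth is unknown. With 9.53% of H3K27me3 peaks at a −log10 q of 5 or more, calls that need weaker peaks, such as that of the immune list, are not firm.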

Other observations

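The tests of X copy number, of an even rate of HEB sites and of 5 escape genes alone were chosen only after the results were seen. The X chromosome held 16613 H3K27me3 peaks, 14.5% of that list, at 99.1 per Mb against 40.8 on the autosomes, of which chromosome 19 had the highest density at 61.0. By base pairs, H3K27me3 peaks covered 24.5% of the X against 14.1% of the autosomes, and chromosome 19 was covered slightly more, at 24.7%. On the X, H3K27ac peaks stood at 7.31 against 25.1 per Mb on the autosomes, H3K4me3 peaks at 3.22 against 6.89 and HEB sites at 0.0477 against 0.364. Of the genes listed beforehand as known to escape X inactivation, Kdm5c, Kdm6a, Eif2s3x, Ddx3x, Pbdc1, 5530601H04Rik, Ftx and Jpx had 0% of their span in H3K27me3 peaks, and Xist, whose RNA coats the inactive X, had 5.02%.

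More copies of an active X were taken to raise every mark. H3K4me3, the higher of the 2 active marks, had 0.4665 times the autosomal density. That density cannot argue against extra copies of the X, active or silenced. Peaks per Mb count marked places and not copies, and a silenced X would add few active marks. More reads of the X would raise −log10 p at matched fold and width. It was 0.988 to 0.997 times that of autosome peaks, which argues against more reads. An inactive X beside an active X would put H3K27me3 at genes with H3K4me3, and 263 of 372 such X genes (70.7%) carried it against 17.4% on autosomes (odds ratio 11.46, two-sided Fisher exact p = 2.20e-108). The 9 escape genes, of which 5 were protein-coding genes with H3K4me3, had a mean of 0.558% of their span covered against 30.2% in 367 protein-coding X genes with H3K4me3 outside that list, a difference of -29.65 percentage points (two-sided permutation test, p = 0.00147). Those 5 alone, the like comparison, had 0% covered (permutation p = 0.0113, a difference of -30.2 percentage points). These values suggest, as a hypothesis, an inactive X in at least part of the cells, and the labels give no group that would test it.

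HEB sites were spread unevenly over the autosomes, as chromosome 15 had 71 H3K27ac peaks with HEB against 43.8 expected (19.9 per 1000 peaks, Fisher exact p adjusted over 19 chromosomes = 0.0015). Random draws of H3K27ac peaks were as uneven in a share of 0.0004, which argues against an even rate. Copy number may contribute, since HEB sites per 1000 H3K27ac peaks rose with the −log10 p of H3K27ac peaks at matched fold and width over the 19 autosomes (two-sided permutation tests, Spearman rho 0.70, p = 0.00109, and Pearson r 0.707, p = 0.00056). Without chromosomes 5 and 15, which lay farthest from the median of that index, r was 0.54 (permutation p = 0.0247) and rho 0.603 (p = 0.0122). Among those left the index ranged only from 0.985 to 1.014, and what it tracks there was not tested. Chromosome 6, the highest of them, had 41 H3K27ac peaks with HEB against 46.2 expected. The labels name no group that would separate copy number from a biological preference.

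The peaks of highest −log10 q on the numbered chromosomes lay at the same place in the 3 mark lists, and no HEB site lay there. For H3K27ac the peak ran on chromosome 2 from 98666286 to 98667483. The folds were 2.01 (H3K27ac), 1.72 (H3K4me3) and 1.05 (H3K27me3), at −log10 q of 10149, 7056 and 1965. High significance at a modest fold is what collapsed repeats would give, as described above for the scaffolds. Whether this place is such a repeat was not tested.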
